A study of Drosophila melanogaster with 3 samples.

How the data were processed

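The samples were 3 biological replicates of chromatin from whole embryos, 0 to 24 h old and of both sexes. The embryos came from transgenic flies that express lilli fused at its C terminus to eGFP. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an anti-GFP antibody, per the labels. Replicate numbers were taken from the labels, which call them biological replicates. There is 1 group, so no test compares conditions and no numbers pair samples.

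Per the file headers, that is the text files deposited beside the lists, each replicate's list of peaks and background was derived from that replicate's alignment and a control alignment, the pooled list from the 3 alignments and the control, and the optimal list from the pooled and replicate lists by the irreproducible discovery rate. The aligner, the peak caller and their versions are not given in the sources used here. Each line gives a peak, its summit, a signal value and a q-value. The signal values are the authors' own per-peak values in the deposited lists, made against the control and not comparable between lists. The deposited -log10 q-values reach the same highest value in 6088 of the 6970 optimal peaks and were not used to rank. The p column holds no values. The 6970 optimal peaks on dm6 were tested to be exactly the 6970 pooled peaks with the highest signal, so the other 23030 pooled peaks are called lower-ranked. Lists of 30000 peaks include background by design. Depth per replicate is unknown, since the lists hold no reads, and signal tracks and alignments were not used here. Intervals on shares of peaks are 95% Wilson intervals over peaks and do not cover differences between embryos.

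Coordinates are 1-based on dm6. The annotation was Ensembl release 115 on the same assembly, and every peak end was checked to lie within the arm's length. Only the arms X, 2L, 2R, 3L, 3R and 4 were analysed, and transposable elements were left out. The dm3 lists were only counted, with no coordinates converted. A summit was assigned to a promoter (within 500 bp of any TSS), otherwise in this order to 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence. A protein-coding gene was bound if an optimal summit lay within 500 bp of any of its TSSs. Other summits are distal. Since the promoter excess lowers every other share, the other locations were also compared among summits outside promoters.

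The strongest 6970 peaks of each replicate were compared by summits within 100 bp, against 100 circular shifts within arms. Locations were compared with 1000 such shifts, two-sided. Bound shares by arm and in 29 gene lists used Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over arms or lists. Genes are not independent replicates, and counts per replicate are given beside the tests. Of the listed names, 6 matched no annotated symbol or repeated another and were not analysed here. Motifs, 12 short words on either strand within 100 bp of the summit, were compared at promoters with 1 window per peak at an unbound promoter at the same signed distance (Fisher's exact test), and at distal peaks with the window 1000 bp to a random side (exact binomial test on discordant pairs), adjusted over the 12 words.

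Gene lists, words, tests and alternatives were fixed before the data were examined, except those alternatives named in the closing part as chosen later. Named genes are those of the 20 optimal peaks with the highest signal (nearest TSS within 1000 bp, otherwise the gene containing the summit), lilli and the genes linked to it, up to 4 bound members per list with the highest promoter signal and all members of lists of up to 9 genes, and up to 3 unbound members in alphabetical order. The neighbours NTPase and cbt, Antp in replicate 3 and genes in the closing part were singled out after their values were seen. Lists built from name patterns also took in Cp190 and Cp110 (egg shell and yolk) and Acp1 and Acp65Aa (seminal fluid and testis), which do not belong there by function, and an added alternative left these out. Alternatives covered summit distance, number of peaks, promoter window, peak middle, gene body, 10000 random lists matched on number of TSSs (up to 3 classes) and 5 classes of gene length, motif window and controls, and leaving out each replicate. For peak sets, leaving out a replicate means optimal peaks found within 100 bp in both others, which leaves 4828 to 5124 peaks and is also a stricter set.

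The steps were tested on simulated data. With 70% of members bound in 3 planted lists among 13945 genes, 79.7% of planted lists were called and 0.167% of other lists. Of 100 shifted peak sets the promoter test called 4%, and all 100 sets with 20% of summits moved to TSSs. A planted overlap of 59.7% was recovered as 59.9%. A word planted in 10% of 3000 random windows was called in every run, and 0.909% of other words were. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.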

Results

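Lilliputian (lilli) is the fly member of the AF4/FMR2 family and a subunit of the super elongation complex, which acts on paused RNA polymerase II. Chromatin immunoprecipitation with sequencing mapped a lilli-eGFP fusion protein in whole Drosophila melanogaster embryos collected from 0 to 24 h, with an antibody against GFP. There was 1 group of 3 biological replicates, so the comparisons below are between replicates, between genomic positions, and between groups of genes. On the dm6 genome the deposited lists held 6970 optimal peaks, 30000 ranked peaks from the 3 replicates pooled, and 30000 ranked peaks for each replicate. The files give peaks and not reads, so the sequencing depth of each replicate is unknown, and no mock or input library was analysed here. A gene called bound has an optimal peak, and signal that open chromatin gives in general was not separated from binding of lilli. Because whole embryos of all these ages were mixed, binding limited to few cells or to a short stage may give no optimal peak.

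The strongest peak lay in an intron of ush, which encodes a Friend-of-GATA cofactor, at 2L from 480554 to 481376. Its signal was 5425, the authors' own value, which is used here only to rank peaks within a list. The next 4 peaks lay upstream of CG14100 (3L, 19590379 to 19590874, signal 5322), upstream of Ugalt, a UDP-galactose transporter gene (X, 2703669 to 2704131, signal 4420), in an intron of CG11050 (2L, 6612437 to 6612959, signal 4170), and 86 bp downstream of the start of Chro, which encodes a protein of interband chromatin and the spindle (3L, 22878662 to 22879167, signal 3714). The remaining 15 of the 20 strongest peaks were assigned to Tcs5, CenG1A, CG8320, PNPase, Lk6, px, CG1888, larp, CG32772, CG9663, Art3, ph-p, Shc, CG9147 and Pal1. Of the 20 peaks, 15 lay at promoters and 5 in introns. None of the 20 ranked below place 37 in any replicate, and 15 were within the first 20 in all 3 replicates.

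The lilli gene itself carried peaks. The flies were transgenic, and the peak lists cannot tell reads of the native gene from reads of a lilli transgene. A peak from 2885556 to 2885960 on 2L (rank 328, signal 811) had its summit 153 bp upstream of a lilli start site and 74 bp downstream of a start site of the neighbouring NTPase gene, so it counts for both genes. It ranked 304, 250 and 453 in replicates 1, 2 and 3. A further 7 optimal peaks lay in lilli introns, the strongest from 2896981 to 2897277 (rank 278, signal 869). Genetic studies have linked the early expression of 3 genes to lilli. Of these, Sry-alpha was bound, with a summit 27 bp upstream of its start (signal 222). The pair-rule gene ftz and the gap gene hkb had no optimal peak within 500 bp of a start site. The embryos were whole and of mixed ages, so binding limited to an early stage or to few cells may go undetected. The lists therefore do not show that lilli is absent from ftz or hkb.

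**Figure D1:**
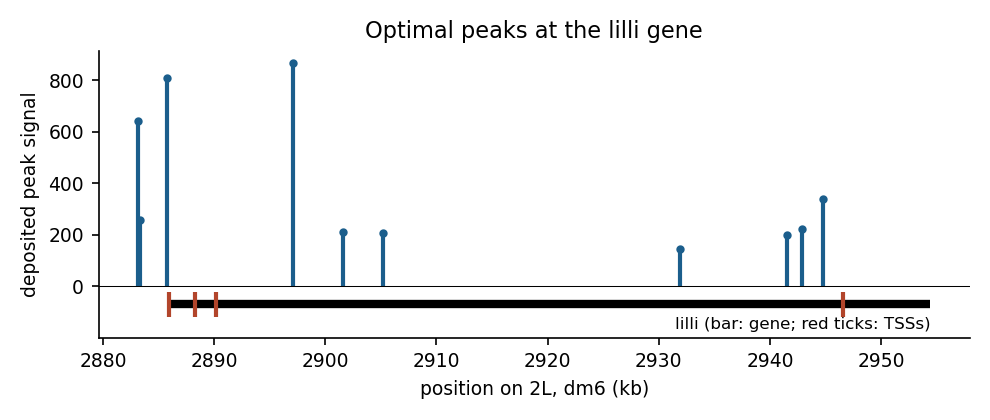
Optimal peaks around lilli on 2L (dm6, position in kb), each drawn as a line at its summit with the deposited signal as height. The black bar is the gene, from 2885929 to 2954406, and red ticks are its 4 annotated start sites. The peak at the left end of the gene has signal 811, and 7 further peaks stand inside it.

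Replicate experiments recovered largely the same strong peaks. Of the 6970 strongest peaks of a replicate, 73.0% ± 2.52 (SD over 3 pairs) had a summit within 100 bp of one of the 6970 strongest peaks of another replicate. Replicates 1 and 2 shared 73.3%, replicates 1 and 3 shared 70.3%, and replicates 2 and 3 shared 75.3%. Shifting the summits along each chromosome arm gave 1.05% on average and at most 1.48% (permutation, one-sided, p = 0.0099, the smallest that 100 shifts can give). Optimal peaks were present among the strongest peaks of a single replicate in 83.5% ± 2.07 (SD, n = 3) of cases, and 4428 of them (63.5%) in all 3 replicates. Signal was also compared across optimal peaks with a summit within 100 bp in the whole lists of both replicates. Spearman's rho was 0.786, 0.756 and 0.820 for the pairs 1 and 2, 1 and 3, and 2 and 3. These were 6494, 6444 and 6518 peaks, which are not independent replicates. The optimal peaks were chosen for reproducibility from these same lists. Their recovery in the replicates and the rho values are therefore partly set by that choice. The share found in every replicate depends on the distance allowed: it was 46.7% within 50 bp and 72.4% within 250 bp.

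Binding was concentrated just upstream of transcription start sites (TSSs). Promoters, taken as 500 bp either side of a TSS, held 3865 optimal summits, or 55.5%, and 55.8% ± 1.76 (SD, n = 3) of the strongest peaks of a replicate. Summits shifted along the arms fell there in 13.6% ± 0.621 (SD over 1000 shifts), a 4.08-fold lower share (permutation, two-sided, p = 0.002, the smallest that 1000 shifts can give). At promoters the median summit lay 77 bp upstream of the TSS, and 77.5% of summits were upstream. The strongest 697 peaks were at promoters in 71.0% of cases (95% Wilson interval 67.5 to 74.3), against 43.8% (40.1 to 47.5) for the weakest 697.

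Coding exons over 500 bp from any TSS were almost free of summits. Coding sequence nearer to a TSS counts as promoter here and was not tallied apart. Coding exons so defined held 12 optimal summits (0.172%), against 13.7% ± 0.665 of shifted summits. They held 0.311% ± 0.0933 (SD, n = 3) of the strongest peaks of a replicate. Because promoters took most summits, the other locations were compared among the 3105 summits outside promoters, a comparison chosen after the shares of all summits were seen. There, coding exons held 0.386% against 15.9% ± 0.830 of shifted summits (SD over 1000 shifts), 3' UTRs 1.93% against 5.13% ± 0.352 and sequence between genes 23.9% against 31.4% ± 1.49, each lower with permutation p = 0.002, two-sided. Introns held 70.8% against 45.7% ± 1.13 and other exons 1.87% against 0.949% ± 0.144, both higher with the same permutation p, and 5' UTRs did not differ past the threshold (1.13% against 0.908% ± 0.131, permutation p = 0.114). The strongest peaks of the replicates outside promoters were in introns in 70.5% ± 0.720 of cases (SD, n = 3), and lower-ranked peaks in 61.1%, with 21.5% of the latter between genes. As shares of all 6970 summits, introns (31.5% against 39.5%) and 5' UTRs (0.502% against 0.784%) were below shifted summits only through the promoter excess. Among the 23030 peaks ranked below the optimal set, 27.8% were at promoters and 6.54% in coding exons.

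**Figure D2:**
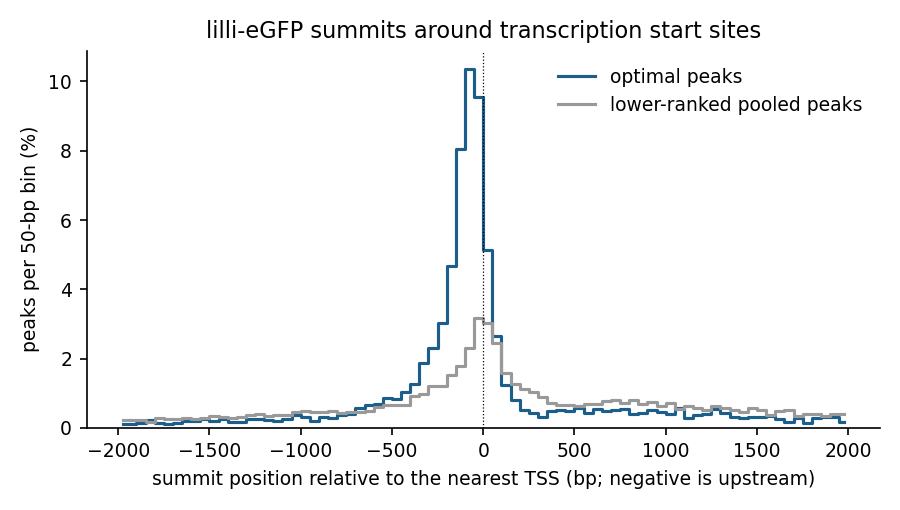
Position of summits relative to the nearest TSS, in 50-bp bins, as a percentage of the 6970 optimal peaks (blue) and of the 23030 lower-ranked pooled peaks (grey). The optimal summits pile up upstream of the TSS, with a median of 77 bp upstream among promoter peaks.

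Summits sat in stretches of low GC content. In a 51-bp window at the summit, GC content was 37.3% for promoter peaks and 33.1% for distal peaks, against 44.9% and 41.1% at 1000 bp away. The strongest peaks of the replicates had 35.9% ± 0.680 (SD, n = 3) at the summit and 43.1% ± 0.104 at 1000 bp. Lower-ranked peaks dipped less, to 41.5% at promoters and 38.9% at distal positions.

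**Figure D3:**
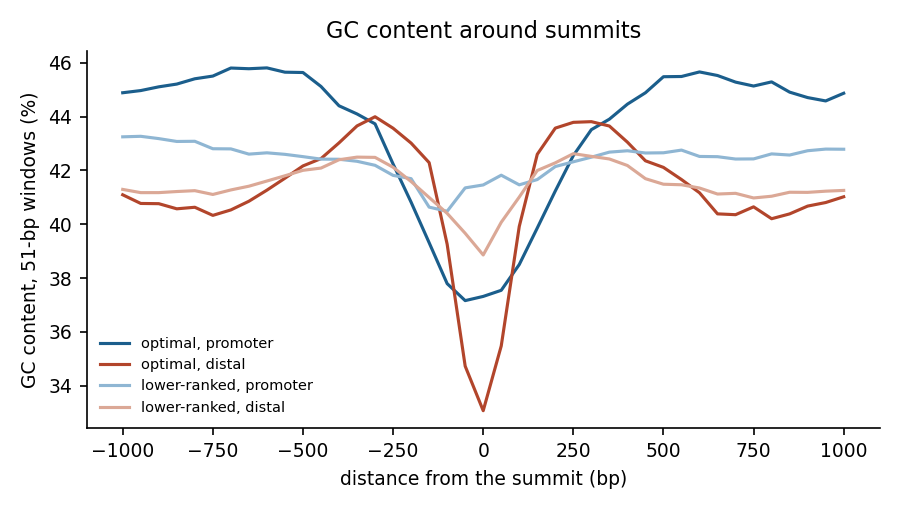
Mean GC content in 51-bp windows (percent) against distance from the summit (bp), for optimal and lower-ranked peaks at promoters and at distal positions. Distal optimal peaks reach the lowest GC content of these 4 sets at the summit, 33.1%.

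A total of 4371 of 13945 protein-coding genes (31.3%) had an optimal summit within 500 bp of a TSS, and 4289 ± 115 (SD, n = 3) had one among the strongest peaks of a replicate. Bound genes were spread over all arms. The share was higher on 3R than on the other arms (33.8% against 30.5%, Fisher's exact test, two-sided, adjusted p = 0.00186) and lower on 2R (29.5% against 31.8%, adjusted p = 0.0494, Fisher's exact test). On 2L it was 30.6%, on 3L 31.1%, on X 31.3% and on 4, where 19 of 80 genes were bound, 23.8%, none past the threshold. The 2R call ended with windows of 250 bp (Fisher's exact adjusted p = 0.0996) or 1000 bp (0.122), with the top 3485 peaks (0.301), and without replicate 1 (0.271), 2 (0.140) or 3 (0.0801). Chromosome 4 passed with the top 3485 peaks (0.0299) and without replicate 1 (0.0424) or 3 (0.0196), and X passed with the top 3485 peaks (7.51e-04), both with lower shares (Fisher's exact test).

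Genes for cytoplasmic ribosomal proteins, Polycomb and Trithorax group genes and elongation factor genes were bound more often than other genes. Of 85 genes for cytoplasmic ribosomal proteins, 67 were bound (78.8%, odds ratio 8.26, Fisher's exact adjusted p = 3.05e-18), and 77.6% ± 3.53 (SD, n = 3) per replicate. The strongest were RpL34b (signal 976), RpS20 (897), RpL7 (874) and RpS27 (830), while RpL10Aa, RpL10Ab and RpL15 were among the 18 without an optimal promoter peak, of which 16 had a lower-ranked one. RpL15 was bound in 2 replicates taken singly. Of 22 Polycomb and Trithorax group genes, 15 were bound (odds ratio 4.71, Fisher's exact adjusted p = 0.00388), and 16, 14 and 15 in replicates 1, 2 and 3. They included ph-p, a subunit of Polycomb repressive complex 1 (signal 2690), the nucleosome remodeller brm (1063), Trl, which encodes GAGA factor (781), and the histone methyltransferase gene E(z) (461). Psc, Sce and Scm were not bound, although Psc was bound in 2 replicates taken singly and Scm in 1. Of 21 elongation factor genes, 14 were bound (odds ratio 4.39, Fisher's exact adjusted p = 0.00623; 13, 17 and 17 in replicates 1, 2 and 3), led by lilli (811) and followed by the NELF subunit genes Nelf-E (590) and Nelf-A (455) and the kinase gene Cdk12 (404). Cdk9 and CycT, which encode P-TEFb, and Eaf were not.

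Hippo pathway genes and insulin and TOR pathway genes were bound more often as well, with less secure calls. Of 12 Hippo pathway genes, 9 were bound (odds ratio 6.58, Fisher's exact adjusted p = 0.00986), among them Mer (signal 592), the coactivator gene yki (510), the kinase gene hpo (453) and kibra (394), with ds, ft and mats without an optimal promoter peak, although mats was bound among the strongest peaks of all 3 replicates. Of 18 insulin and TOR pathway genes, 11 were bound (odds ratio 3.45, Fisher's exact adjusted p = 0.0318), among them Pi3K21B (803), the receptor gene InR (493), Rheb (490) and Thor (469), with Lnk, Myc and Pi3K92E unbound. With peaks required in both other replicates, the insulin and TOR call ended without replicate 1 (Fisher's exact adjusted p = 0.239), 2 (0.623) or 3 (0.217). It ended as well against random lists matched on gene length and number of TSSs (ratio 1.48, permutation adjusted p = 0.229, range over alternatives 0.00177 to 0.913). The Hippo call ended without replicate 1 (odds ratio 0.972) or 2 (1.04) and with windows of 250 bp (3.99), and held with windows of 1000 bp (20.5), although 9, 10 and 7 of its genes were bound in replicates 1, 2 and 3. The Polycomb and Trithorax call held without replicate 2 (odds ratio 3.13) and with peaks anywhere in the gene (8.84), and ended without replicate 1 (2.92, adjusted p = 0.0638, Fisher's exact test) and with the top 3485 peaks (0.119), with which the Hippo and the insulin and TOR calls (0.628 each) ended as well.

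Chemoreceptor genes, seminal fluid and testis genes and egg shell and yolk genes were rarely bound. Of 179 chemoreceptor genes 2 were bound, Ir60e and Gr63a (odds ratio 0.0243, Fisher's exact adjusted p = 4.77e-25). Of 65 seminal fluid and testis genes 2 were bound, Sfp26Ad and Mst36Fa (odds ratio 0.0691, Fisher's exact adjusted p = 1.35e-07). Both calls held without replicate 1 (odds ratios 0.0161 and 0.0453) and with peaks anywhere in the gene (0.0638 and 0.115), and that of the chemoreceptors in windows of 250 bp (0.0157) and 1000 bp (0.0417). Of 20 genes matched as egg shell and yolk genes 1 was bound, Cp190 (Fisher's exact adjusted p = 0.027), which encodes an insulator protein and matched by its name alone. Without the misnamed Cp190 and Cp110 none of 18 was bound (Fisher's exact adjusted p = 0.00653). The call with all 20 ended with windows of 250 bp (Fisher's exact adjusted p = 0.0992), with the top 3485 peaks (0.512), without replicate 1 (0.121), 2 (0.181) or 3 (0.109) and against random lists matched on gene length and number of TSSs (permutation adjusted p = 0.0723). None of the 111 genes of the replication-dependent histone repeat had an optimal promoter peak (Fisher's exact adjusted p = 7.69e-18), but this test does not bear on binding. Of the 31-mers of these near-identical copies, 0.951% were unique in the genome. Among 130 other genes with under 10% unique 31-mers at all their TSSs, 0 had a pooled promoter peak.

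Among genes with any peak of the pooled list at a promoter, 7673 in all, of which 57.0% were bound, 1 of these 9 calls held, that of the ribosomal proteins (67 of 83, odds ratio 3.20, Fisher's exact adjusted p = 1.45e-04). The elongation (14 of 19, adjusted p = 0.376), Polycomb and Trithorax (15 of 20, 0.326), Hippo (9 of 12, 0.436), insulin and TOR (11 of 17, 0.913), chemoreceptor (2 of 11, 0.078) and seminal fluid and testis (2 of 9, 0.198) lists did not pass (Fisher's exact test), the neural list described next passed below other genes (0.0416), and the histone and egg shell lists had fewer than 3 members there. In a further comparison chosen after the data were seen, genes with the DNA replication-related or Ohler 1 word within 100 bp of a TSS were left out, and the elongation (6 of 11, odds ratio 3.06, adjusted p = 0.20) and Hippo (5 of 8, 4.25, 0.145) calls ended (Fisher's exact test). The insulin and TOR (11 of 15, odds ratio 7.03, adjusted p = 0.00177), Polycomb and Trithorax (13 of 15, 16.6, 2.31e-05), ribosomal protein (41 of 53, 8.80, 1.33e-12) and egg shell (0 of 18, 0.0138) calls and the other 3 held (Fisher's exact test). Of these 3, the histone call does not bear on binding, as stated above.

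No list of embryonic patterning genes passed the test. For the smallest lists a call below other genes was out of reach. The fewest possible bound, 0 of 8 homeotic genes, gave p = 0.0635 before adjustment (Fisher's exact test). As for ftz and hkb above, binding limited to a short stage or to few cells may be missed in these lists. No homeotic gene (lab, pb, Dfd, Scr, Antp, Ubx, abd-A and Abd-B) was bound (0 of 8, Fisher's exact adjusted p = 0.142), and of 21 genes of the nervous system and glia 2 were bound, the neuronal RNA-binding protein gene elav (signal 1657) and Syt1 (129), at an adjusted p of 0.0793 (Fisher's exact test). Against random lists matched on gene length and number of TSSs both passed, with permutation adjusted p = 0.0418 and 0.0139. Over all alternatives the adjusted p ran from 0.0418 to 1 for the homeotic genes, where Antp was bound in replicate 3, and from 0.0139 to 0.512 for the neural genes (exact or permutation tests), which also passed with windows of 1000 bp (0.0339). Of 14 maternal, head and gap genes bcd was bound, of 9 pair-rule genes hry was bound (eve, ftz, odd, opa, prd, run, slp1 and slp2 were not), of 5 cellularization genes Sry-alpha was bound (bnk, halo, nullo and slam were not), and of 13 segment polarity genes nkd, smo and arm were bound. Of 24 dorsoventral genes 5 were bound, of 11 Dpp pathway genes 3, of 8 JAK/STAT genes 2 (dome and chinmo; Socs36E, Stat92E, hop, upd1, upd2 and upd3 were not), of 16 gut, fat body and blood genes 3, of 13 epidermis and trachea genes 3, and of 4 cell death activators hid (grim, rpr and skl were not).

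Other signalling and tissue lists did not pass the test at promoters. Of 19 Notch pathway genes 11 were bound, led by gro (signal 1205) and E(spl)m3-HLH (572), at Fisher's exact adjusted p = 0.0593, and against matched lists they passed (permutation adjusted p = 0.0232, range over alternatives 0.0232 to 0.926). Of 17 muscle genes 10 were bound, led by sls (729) and Mlc2 (426), at Fisher's exact adjusted p = 0.0555, or 0.0417 without replicate 2 (range over alternatives 0.0417 to 0.926). In the ecdysone response 6 of 11 genes were bound, against 6.14 on average in matched lists. With peaks anywhere in the gene or within 1000 bp it was 11 of 11 (Fisher's exact adjusted p = 2.82e-04), a comparison not matched on gene length. Bound genes numbered 9 of 19 in the Ras and MAPK pathway, 8 of 20 among heat shock genes and 4 of 11 in the germ line. Of 48 proteasome genes 21 were bound (permutation adjusted p = 0.0418 against matched lists). The 48 include variant genes such as Prosalpha1R, Prosalpha3T, Prosbeta2R1 and Rpt3R, none of them bound. The proteasome list was not tested without such variants. Hsp27 (1133), Hsp26 (534), Hsp83 (507) and stv (487) were the strongest heat shock genes. The Hsp70 genes, which are near-identical copies, had no optimal promoter peak. They count among the 20 heat shock genes, and the list was not tested without them.

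**Figure D4:**
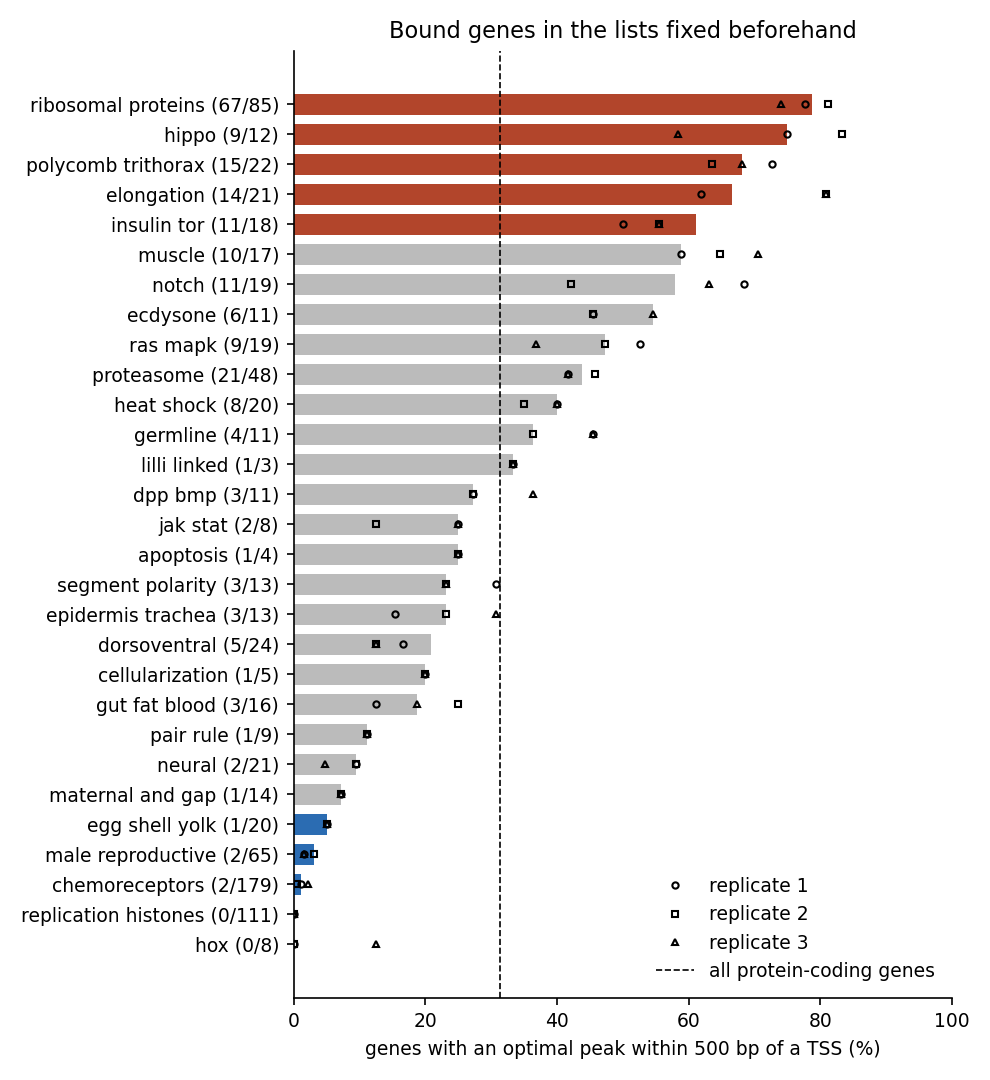
Percentage of genes with an optimal peak within 500 bp of a TSS in each of the 29 gene lists (bars, with bound and total genes in brackets), red for lists above and blue for lists below other genes at adjusted p under 0.05, grey otherwise. Open symbols give the percentage from each replicate, and the dashed line marks 31.3% for all protein-coding genes.

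Promoter peaks were rich in words of housekeeping core promoters. The DNA replication-related element, TATCGATA, was within 100 bp of 9.44% of 3865 promoter summits (95% Wilson interval 8.56 to 10.4) and of 3.05% of windows at unbound promoters at the same distance to the TSS (ratio 3.09, Fisher's exact adjusted p = 3.77e-31), with 9.06% ± 0.438 (SD, n = 3) over the strongest peaks of the replicates. The Ohler 1 element, GGTCACACT, bound by M1BP, was at 4.24% against 2.10% (ratio 2.02, Fisher's exact adjusted p = 3.11e-07). The size of both differences depended on the controls: ratios were 16.6 and 8.63 against windows 1000 bp away, 2.27 and 1.56 with GC-matched controls and 2.16 and 1.33 against lower-ranked peaks, all past the threshold. Also more frequent was the E-box CAGCTG, at 12.5% against 10.5% (adjusted p = 0.0117, Fisher's exact test), a call that ended within 50 bp of the summit (ratio 0.977). The initiator TCAGTY was less frequent (17.5% against 26.6%, Fisher's exact adjusted p = 1.59e-21; not against windows 1000 bp away, ratio 1.06), as was the Zelda site CAGGTA (3.60% against 4.63%, adjusted p = 0.0435, Fisher's exact test), a call that ended within 50 bp (0.543) or 200 bp (0.150). The pause button was less frequent (8.75% against 11.7%, Fisher's exact adjusted p = 6.44e-05) and the AT-rich word AATTAATT more frequent (3.34% against 2.35%, adjusted p = 0.0224), and both calls ended with controls matched on GC content (0.689 and 0.318, Fisher's exact test). The pause button call also ended within 200 bp (0.171), and the AT-rich call within 50 bp (0.131), with the top 3485 peaks (0.0635) and against lower-ranked peaks (0.0844, all Fisher's exact test). GAGA, TATA, CA-repeat and GATA words did not pass within 100 bp of the summit against unbound promoters, and their calls depended on the window and the controls. An arbitrary control word passed in no alternative. TATA words were at 32.5% of promoter summits, against 30.6% at unbound promoters, 19.4% in windows 1000 bp away (ratio 1.67, exact binomial adjusted p = 8.18e-39), 26.9% at lower-ranked promoter peaks (ratio 1.21, Fisher's exact adjusted p = 7.19e-09) and 35.6% at unbound promoters matched on GC content (ratio 0.912, adjusted p = 0.00795, Fisher's exact test). They also passed within 200 bp (ratio 1.09) and at peak middles (1.08). GAGA words were less frequent than within lower-ranked peaks (ratio 0.806), within 50 bp (0.851), against windows 1000 bp away (0.908) and at peak middles (0.912), and more frequent within 200 bp (1.07) and with GC-matched controls (1.11), all past the threshold. CA repeats were less frequent against windows 1000 bp away (0.730) and lower-ranked peaks (0.573), and more frequent within 200 bp (1.29) and with GC-matched controls (1.41), all past the threshold. GATA words passed below controls at peak middles (0.733) and with GC-matched controls (0.736). Without replicate 1 GAGA (Fisher's exact adjusted p = 0.0395) and GATA (0.0392) passed, without replicate 2 GATA (0.0234), and without replicate 3 TATA (0.0457).

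At the 3105 distal peaks, which lay a median of 2409 bp from a TSS, housekeeping words were rare. The DNA replication-related element was in 0.548% of summit windows and 0.580% of windows 1000 bp away, and the Ohler 1 element in 0.290% and 0.386%, neither past the exact binomial test. TATA words were more frequent at summits (35.7% against 23.9%, exact binomial adjusted p = 9.64e-23), and pause buttons (5.54% against 8.86%, adjusted p = 2.73e-06), E-boxes (5.76% against 8.02%, adjusted p = 0.00158) and CA repeats (3.51% against 5.80%, adjusted p = 1.16e-04) less frequent, by the same exact test. The E-box call ended without replicate 2 (exact binomial adjusted p = 0.428), within 200 bp (0.530) and with the top 3485 peaks (0.111), and the CA-repeat call within 200 bp (0.883) and against lower-ranked peaks (0.121, Fisher's exact test). GAGA words were less frequent within 50 bp (ratio 0.751) and more frequent within 200 bp (1.14) and with GC-matched controls (1.15), all past the threshold. Against windows matched on GC content none of the 4 calls of TATA, pause button, E-box and CA repeat held, with exact binomial adjusted p from 0.0677 for TATA to 0.484 for the E-box.

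The same libraries mapped to the older dm3 genome gave 6719 optimal peaks, 251 fewer than on dm6. Each arm had more optimal peaks on dm6, from 1.03 times as many on X to 1.04 times on 3R among the 5 large arms, and 28 against 26 on chromosome 4. No test applies to this count, since both lists come from the same reads.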

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

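On the dm3 genome, some peaks fell on heterochromatic or unplaced sequences that the comparisons above do not use. There were 50 such peaks in the pooled list, and 54, 62 and 56 in the lists of replicates 1, 2 and 3. These lists include background by design, and 1 such peak was in the optimal dm3 list. With 3 replicates in 1 group, no test for single outlying replicates was made. No biological explanation was tested.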

How the results depend on the processing

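Among these alternatives, the shift span, the summits outside promoters, the comparisons with lower-ranked peaks, the background of genes with a pooled peak, the genes without the DNA replication-related or Ohler 1 word, the lists without misnamed members and the distal GC controls, were chosen after seeing the data. Of 707 values under alternatives for 70 results, 568 kept direction and side of the threshold (or stayed within the spread), 49 fell below it, 24 passed it, 16 moved and 50 changed direction. Replicate overlap, the excess at promoters and the lower shares in coding exons and 3' UTRs kept both under all alternatives run. The lower shares in introns and 5' UTRs came from the promoter excess by construction: outside promoters their ratios were 1.55, past the threshold, and 1.24. Sequence between genes was below shifted summits there, but held more of the optimal (23.9%) than of the lower-ranked summits (21.5%). The overlap ran from 47.4% (all peaks) to 81.8% (peaks overlapping by 1 bp) and the promoter excess from 1.99-fold (against lower-ranked peaks) to 6.14-fold (250 bp window). Optimal peaks found in every replicate were 35.0% with 3485 peaks per replicate, by the shorter lists, 90.0% with all peaks, 46.7% within 50 bp, 72.4% within 250 bp, and 69.3 to 73.5% without single replicates, where 2 lists need to match. Mean rho was 0.756 to 0.820 without single replicates. Arms called were 1 with windows of 250 or 1000 bp and 1 to 2 without single replicates. With the top 3485 optimal peaks 2677 genes were bound and 5 lists called, by the smaller set. Lists called were 2 among genes with a pooled peak, and 5 to 7 without single replicates (5 without replicate 1). Distal words called were 1 with GC-matched controls. The cause was not tested for the other changes. Odds ratios of lists, none past the threshold in either setting, changed side as follows: in windows of 1000 bp, lilli-linked 0.929, Dpp 1.55 and JAK/STAT 1.11; in windows of 250 bp, Dpp 1.07; with gene bodies, lilli-linked 0.696, segment polarity 1.62, dorsoventral 1.65, Dpp 3.71, JAK/STAT 1.39 and epidermis 1.19; with the top 3485 peaks, cellularization 1.05, ecdysone 0.935 and apoptosis 1.40; as ratios to matched lists, ecdysone 0.978 and apoptosis 1.10; among genes without the 2 words, germ line 0.850. With gene bodies all 12 Hippo and all 11 ecdysone genes had a peak, so no odds ratio could be given. Both lists passed, ecdysone unlike at promoters (adjusted p = 2.82e-04, Fisher's exact test), with no matching on gene length. Without single replicates Hippo ran from 0.972 to 5.93, from a called main value, and apoptosis from 0.972 to 1.04. Ratios of promoter words changed side for GAGA (1.07 within 200 bp, 1.11 with GC-matched controls, both past the threshold), Initiator (1.06 against flanks), TATA (0.994 within 50 bp, 0.912 GC-matched, the latter past it), E-box (0.977 within 50 bp) and CA repeat (0.804 within 50 bp, 0.730 against flanks, 0.944 with the top 3485 peaks, 0.573 against lower-ranked peaks, the flank and lower-ranked values past it, 0.920 to 1.01 without single replicates). Ratios of distal words changed side for GAGA (1.14 within 200 bp, 1.03 against lower-ranked peaks, 1.15 GC-matched, the first and last past it), Zelda (0.966 within 200 bp), the replication element (1.13 at peak middles), Ohler 1 (1.55 lower-ranked, 1.29 GC-matched), Initiator (1.05 within 200 bp, 1.01 at peak middles, 1.01 lower-ranked), AT-rich (0.896 within 200 bp, 0.875 GC-matched, 0.951 to 1.08 without single replicates), GATA (0.956 within 50 bp) and the control word (1.11 within 200 bp, 1.19 lower-ranked, 1.5 GC-matched, 0.667 to 1.5 without single replicates). The dm3 lists gave 6719 optimal peaks. No paired analysis was possible because there is 1 group. Depth is unknown and the embryos were whole and of mixed ages, so a gene without a peak is not shown to be unbound.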

Other observations

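The tests of lower-ranked coding-exon peaks, of peaks below the threshold, of lists among genes without the words and of short words were chosen after the values or the pattern had been seen, and the others before their results. Matched lists were an alternative fixed beforehand, but their use to weigh the neural genes was chosen afterwards. The gene with the most optimal peaks was kirre, which encodes a myoblast adhesion protein and held 23 over 394 kb. Next came shn and CG1677 with 16 each, pnt, sbb and ush 14 each, Tlk and tara 13 each, and CHES-1-like and Raf 12 each. CHES-1-like spans 27.0 kb. lilli held 7, and 17 of the 199 genes of 50 to 90 kb (8.54%) held as many, with a median of 1. Among genes for small RNAs, 10 of 32 snRNA genes (31.3%, 95% Wilson interval 18.0 to 48.6) had a peak within 500 bp of a start, with 30.2% ± 4.77 (SD, n = 3) per replicate. The shares were 11.5% of 269 snoRNA genes, 8.62% of 290 tRNA genes and 9.32% of 3261 ncRNA genes, and none of 99 rRNA genes had one. Whether reads can be placed in the rRNA genes was not tested.

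Few optimal summits lay in coding exons outside promoters, that is over 500 bp from any TSS. Distal positions drawn with the same GC content as distal summits lay in coding exons in 4.65% ± 0.341 of cases (SD over 100 draws), against 0.386% of the distal summits and 15.8% of distal positions without matching. Matching on GC content therefore narrowed the gap and did not close it. Whether GC content causes any part of the gap cannot be told from this, since the position of the summits also sets their GC content. Lower-ranked peaks of the same calling, which include background, lay in coding exons in 6.54% of all cases and in 9.07% of those outside promoters. The calling and the control therefore did not leave coding exons out altogether. That 9.07% was below the 15.9% of shifted summits outside promoters, so a partial loss of exon peaks stays open. Whether other proteins show the same gap was not tested, and no biological explanation was tested.

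Homeotic and neural genes, singled out from the 29 lists for few bound members, were bound in 2 of 29 cases. Matching on TSS number and gene length left the neural list past the threshold (permutation adjusted p = 0.0139). Fisher's exact test without matching gave 0.0793, and alternatives ran from 0.0139 to 0.512 (exact or permutation tests). Matched lists held 8.56 bound genes on average against 2 of 21 neural genes, and 3.62 against 0 of 8 homeotic genes. Lists with these 2 traits thus held more bound genes than were seen. The permutation p takes no account of the choice of the list, so it does not settle the reason. None of the 29 has the DNA replication-related or Ohler 1 word near a TSS. Other genes without these words were bound in 28.2% of cases, against 6.90% of the 29 (Fisher's exact p = 0.0112). For the neural list the odds ratio was 0.230 among all genes and 0.268 among genes without the words. Leaving out genes with the words thus left the odds ratio of the neural list nearly unchanged. Because the lists were chosen for few bound members, this does not decide whether a lack of the words is a reason. The p of 0.0112 takes no account of the choice of lists. Adjusted over all lists among genes without the words it was 0.20 for the neural and 0.240 for the homeotic list (Fisher's exact test). The homeotic list could not have passed there, since 0 of 8 bound gave p = 0.116 before adjustment (Fisher's exact test). Whether the gap exceeds what this choice would give stays open. Binding limited to few cells or to a short stage stays open too, since whole embryos of mixed ages may not show it. Unbound members had a lower-ranked promoter peak more often than other unbound genes (17 of 27 against 34.4%, Fisher's exact p = 0.00354), but against unbound genes matched on TSS number and gene length the excess was not past the threshold (13.9 ± 2.38 expected, SD over 10000 draws, permutation p = 0.281, two-sided), so signal below the threshold stays open as an explanation. No biological explanation was tested.

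The replication-dependent histone repeat on 2L, from 21416953 to 21541681, had no summit in the pooled list or in any replicate list. Of its 31-mers, 0.951% were unique in the genome, against a median of 100% in 1000 random windows. Among 130 other genes with under 10% unique 31-mers at all their TSSs, 0 had a pooled promoter peak, against 56.6% of genes with 90% or more. The absence of peaks is consistent with reads that could not be placed among the copies, so it does not show that lilli is absent there. The read length is not given in the sources used here, and no biological explanation was tested.

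Short words were searched for on 2L, 2R and X and tested on 3L, 3R and 4, although similar words had been seen in an earlier look at all arms. All 10 words taken were more frequent at held-out summits than 1000 bp away (exact binomial test, adjusted over 10). They are not 10 separate findings. ATCGATAG overlaps the DNA replication-related element, and GGTCACAC lies within the Ohler 1 element, both tested above on all arms. Several of the other words share CAGTG or its reverse complement CACTG. At promoters, ATCGATAG was at 8.73% of 1730 held-out summits against 0.462% (adjusted p = 2.45e-34, exact binomial test), CAACACTG at 5.03% against 0.636%, and CAGCCCTG at 3.70% against 0.462%. At distal peaks, CACTGAGA was at 5.60% of 1358 held-out summits against 0.810% (adjusted p = 4.65e-13, exact binomial test) and CAGTGTAG at 2.36% against 0.295%. GAGAGAAA, which contains a GAGA word, was at 5.45% against 1.91%, although GAGA words did not pass at distal summits within 100 bp. The flanking windows were not matched on GC content, and those of promoter summits were not chosen to lie at promoters. Words common to promoters in general, bound or not, could therefore pass at promoter summits. The promoter words were not compared with unbound promoters. For the DNA replication-related element the ratio was 16.6 against flanking windows and 3.09 against unbound promoters. Which proteins bind these words was not tested.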
